A study of Drosophila melanogaster x Drosophila simulans with 3 samples.

How the data were processed

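Messenger RNA was measured in heads of female F1 hybrids between Drosophila melanogaster and Drosophila simulans. Mothers came from the D. melanogaster strain Berlin and fathers from the D. simulans strain C167.4. Per the labels' protocols, virgin females were frozen as young adults, heads were separated from bodies with sieves, and each of the 3 independent replicates pooled 200 flies. Polyadenylated RNA was selected with oligo dT beads, fragmented and copied into cDNA with random hexamers, and each replicate was sequenced in a lane of its own on an Illumina GAIIX as 54 bp paired ends. Lane and replicate were therefore the same division of the data. A genomic DNA control from hybrid bodies is named in the series' design text and was not analysed here.

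The deposited count tables listed 60040 exonic regions per library and gave raw, unnormalised counts of reads in 10 classes, per the file headers. In 2 classes a read matched both species' references equally well, and these reads were unassigned. In 4 classes per allele the read matched the reference of one species only, or matched it better than the other, either exactly or with mismatches. Reads are thus placed on one genome or on both, and only the second kind rests on a direct comparison of alignments. Bowtie is the aligner named in the submitters' processing notes. Its version, the genome build, the annotation, the mismatch limits, and whether a count is a read or a read pair are not given in the sources used here. Per the file headers, the authors also gave the percent identity of each region between the species, the percent of positions altered in each strain's reference, and a coverage signal per region and genotype whose origin is not stated. These columns and the region lengths were identical in the 3 tables, and they describe regions, not libraries.

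Per library and region, the 4 classes of each allele were summed. A region was tested when it had a mean of at least 20 allele-assigned reads per library. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) over the 6 allele columns, with replicate as a block and allele as the coefficient. Replicate was used as a block because both alleles of a library come from the same RNA pool. Both alleles of a library shared 1 library size and no scaling was applied between alleles, so a log2 ratio of 0 means equal read numbers. Positive ratios mean more D. melanogaster reads. A region was called at a Benjamini-Hochberg adjusted p under 0.05. Only 2 residual degrees of freedom were left per region, so the spread between libraries was estimated largely from all regions together, with a median of 776 prior degrees of freedom and a common dispersion of 0.00321. Standard errors are the fitted log2 ratio divided by the square root of its F statistic. Ratios of single libraries used a pseudocount of 0.5. Intervals on shares are 95% exact binomial intervals for libraries and 95% Wilson intervals for classes of regions. The first cover the counting error of reads and the second that of regions, and neither covers the spread between libraries. Reads carried no molecular identifiers.

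The procedure was tested on simulated data with the means and library sizes of the 33303 tested regions, 200 of them altered. It recovered 8 of 50 regions altered 1.25-fold, 28 of 50 altered 1.5-fold, 38 of 50 altered 2-fold and 50 of 50 altered 4-fold. Of 33103 unaltered regions, 6 were called. Every region was simulated with the same dispersion of 0.003, and few were altered, whereas 35.6% of the real regions were called. These counts therefore do not give the recovery or the rate of false calls in the real data. As an example of precision, 30 of 60 reads, the smallest total that passes the filter over 3 libraries, gives a 95% Wilson interval of 37.7% to 62.3%.

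All 3 libraries belonged to 1 group, so every comparison was between the alleles within a library. The species of an allele and the parent that transmitted it are the same division of the data in this cross. The deposited tables do not pair region identifiers with genes or coordinates, and the annotation used here does not hold those identifiers. Results are therefore given per exonic region, and identifiers are printed for 2 regions per direction only. Tests per gene, of differences between exons of a gene, of preset gene lists and of chromosomes had been planned and were not run for that reason. The rule for naming regions was set before the data were examined. It took the 10 regions per direction with the largest ratio among called regions with the same direction in all 3 libraries, at least 100 allele-assigned reads and at least 4 reads of each allele in every library. It also took the 5 called regions per direction with the most reads and the same direction in all 3 libraries, and the 3 per direction with the most reads among those with no read of the other allele. The first of the first list and the first of the second list are printed by identifier, and the others by length.

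Alternatives set before the data were examined were TMM scaling and DESeq2 size factors between the columns, the DESeq2 Wald test (DESeq2 1.42.0), exact binomial tests in each library, other filters, the strictest read classes (an exact match to one genome and no placement on the other), a fit without the block, a test against a minimum log2 ratio of 0.5, leaving out each replicate in the region test and, for the share of reads, leaving out the 100 regions with the most reads. Comparisons of reads placed on one genome with reads placed on both, and comparisons by sequence identity, were added after seeing the data. Lengths of joined mitochondrial exons were taken from the BDGP6 annotation, also after seeing the data. Of the tests in the closing section, those of the difference between read kinds, 1 of them by identity, and the first placement test of the regions at mitochondrial lengths were set before their own results were seen. Descriptive statistics used Python 3.11.15 with scipy 1.17.1.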

Results

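Gene expression from each parental allele was compared in hybrid heads, with 3 libraries from independent pools of virgin F1 females. Each female inherited a D. melanogaster genome from the mother and a D. simulans genome from the father, X chromosomes included, so both alleles of a region were read in the same cells. The libraries held 26406916, 26601075 and 29004108 reads over 60040 exonic regions. Reads that matched both species equally made up 30.7%, 31.7% and 29.8% of these. The remaining 18304480, 18157586 and 20364709 reads were assigned to an allele. Replicate 2 stood apart in match quality, with 31.0% of its reads in classes with an exact match against 63.7% and 57.3% in replicates 1 and 3.

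The first comparison asked whether the 2 parental genomes contributed equal numbers of reads. The D. melanogaster alleles contributed more in each library. Their share of assigned reads was 53.9% ± 0.416 (SD, n = 3), and the 3 libraries gave 54.2%, 54.1% and 53.5%, with exact binomial intervals narrower than the spread between libraries. The median tested region also leaned to D. melanogaster in each library, by 0.10, 0.10 and 0.08 on the log2 scale. With 3 libraries, a two-sided exact sign test cannot go below p = 0.25, and no other test of the direction across libraries was run. The excess depended on few regions in part. Without the 100 regions with the most assigned reads, the share was 51.9%. Reads were concentrated, since the 10 regions with the most reads held 18.7% of assigned reads and the 1000 with the most held 56.4%.

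The second comparison asked which exonic regions had unequal expression of the alleles, the question named in the series title. Of the 33303 regions with enough reads, 11851 (35.6%) showed allelic imbalance in read numbers. D. melanogaster reads were in excess in 7799 of these and D. simulans reads in 4052. Read numbers were not corrected for differences in how reads of the 2 species are placed, as the genomic DNA control was not analysed. An imbalance called here is therefore not by itself unequal expression. Most imbalances were modest, with a median absolute log2 ratio of 0.66 in called regions, or 1.58-fold. An imbalance of 2-fold or more was found in 3265 called regions, 2301 toward D. melanogaster and 964 toward D. simulans, and one of 4-fold or more in 810 and 300. The direction was the same in all 3 libraries for 11522 (97.2%) of the called regions, which is no independent check, since the calls rest on the same libraries. Chance alone gives 25%, and 33.2% of the regions not called had the same direction in all 3.

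These calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The DESeq2 Wald test, which takes the spread between libraries differently, called 5927 regions, all of them called by edgeR in the same direction. The split between the species depended on scaling. D. melanogaster made up 65.8% of calls without scaling between alleles and 52.5% with TMM scaling, which shifted the median region by -0.09.

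**Figure D1:**
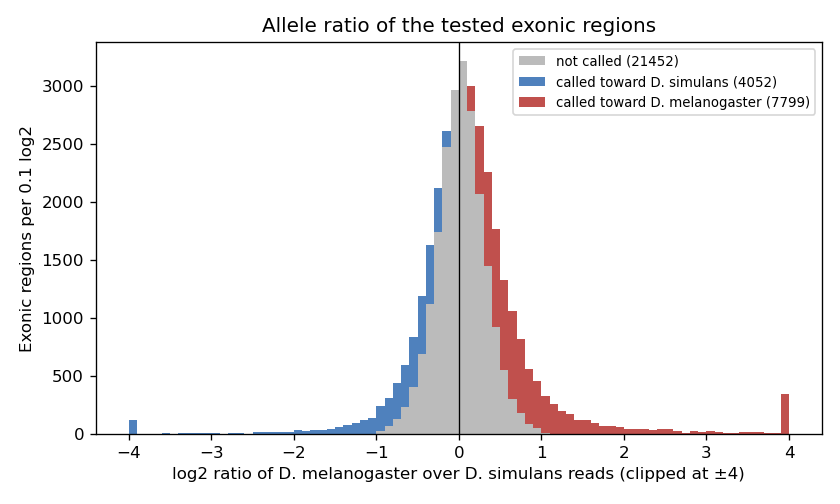
Number of tested exonic regions (vertical axis, regions per 0.1 log2) by log2 ratio of D. melanogaster over D. simulans reads (horizontal axis, clipped at 4 in each direction), stacked as 21452 regions not called, 4052 called toward D. simulans and 7799 called toward D. melanogaster. The distribution is centred near 0 with a median of 0.09, and called regions outnumber the rest beyond the central peak on both sides.

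Some imbalances left almost no reads from one species. F8_SI, an exonic region of 1685 bases with 95.85% identity between the species, was read almost entirely from the D. melanogaster allele, at 99.97% ± 0.0048 of assigned reads (SD, n = 3) and a log2 ratio of 11.91 ± 0.06 (SE). The length of F8_SI equals that of a block of joined mitochondrial exons in the BDGP6 annotation, and the mitochondrial genome is inherited from the mother. Among regions with at least 4 reads of each allele and 100 in all in every library, the 10 largest ratios toward D. melanogaster ranged from 7.39 to 11.91, and 6 of these 10 regions were abundant regions with such lengths. In the other direction, S32496_SI, a region of 740 bases with 99.59% identity, had a D. melanogaster share of 0.353% ± 0.169 (SD, n = 3) and a log2 ratio of -8.00 ± 0.08 (SE). Under the same read limits, the 10 largest ratios toward D. simulans ranged from -5.26 to -8.00. Nearly all assigned reads of S32496_SI were placed on the D. simulans genome only, and too few were placed on both genomes for a test there. Those few leaned the other way, with 14, 6 and 0 D. melanogaster reads in replicates 1, 2 and 3 against 2, 1 and 0 D. simulans reads. For F8_SI the direction held, as D. melanogaster took 99.96% ± 0.00598 (SD, n = 3) of the reads placed on both genomes. Unassigned reads of S32496_SI numbered 68, 110 and 28 in replicates 1, 2 and 3. Those placed on the D. simulans genome only numbered 8325, 12078 and 3203. So few unassigned reads at 99.59% identity mean that its ratio may reflect lost placement on the D. melanogaster genome. This was not tested for S32496_SI alone.

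Some regions had no read of the other allele in any library, 188 with D. melanogaster reads only and 43 with D. simulans reads only. Among the first, a region of 171 bases had 7323 D. melanogaster reads, which is at least 2441-fold higher than a floor of 3 counts over the 3 libraries. Among the second, a region of 533 bases had 2518 D. simulans reads, at least 839-fold higher by the same floor. These are bounds on read numbers and not on expression, as placement was not corrected for. Counting the regions with a few reads of the other allele, 264 regions had at least 98% D. melanogaster reads and 70 had at most 2%.

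The called regions with the most reads included small and almost complete imbalances. F19_SI, of 2248 bases in D. melanogaster and 97.6% identity, alone held 8.54%, 6.97% and 5.69% of assigned reads in the 3 libraries. Its D. melanogaster share was 58.6% ± 1.67 (SD, n = 3), with a log2 ratio of 0.50 ± 0.02 (SE) and an edgeR adjusted p of 2.7e-83. The adjusted p was 0.0079 in edgeR without the block and 9.0e-08 in the DESeq2 Wald test. It was 0.81 in edgeR against a minimum log2 ratio of 0.5. The direction toward D. melanogaster was not shared by its reads placed on one genome only. Of these, D. melanogaster took 3.53% ± 0.465 (SD, n = 3), against 90.6% ± 1.43 of the reads placed on both. The next region by reads toward D. melanogaster, of 2304 bases, had a share of 54.5% ± 0.901 (SD, n = 3). The other 3 of the 5 with the most reads were a region of 1536 bases at 99.96% ± 0.0114, a region of 844 bases at 56.2% ± 0.229 (SDs over n = 3) and F8_SI. The 1536-base region and F8_SI were at mitochondrial lengths.

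Of the regions called toward D. simulans, the one with the most reads was S14812_SI, of 1285 bases in D. melanogaster. It had a D. melanogaster share of 48.6% ± 1.15 (SD, n = 3). Its log2 ratio was -0.08 ± 0.03 (SE) with an edgeR adjusted p of 0.0051, and the adjusted p was 0.40 in edgeR without replicate 1, 0.68 in edgeR without the block and 0.25 in DESeq2, in a range of 4.8e-21 to 1 over all alternatives. Larger D. simulans excesses were found in a region of 7166 bases, with a D. melanogaster share of 42.9% ± 0.548 and a log2 ratio of -0.41 ± 0.03 (SE), and in a region of 2119 bases, with a share of 44.7% ± 0.489 and a log2 ratio of -0.31 ± 0.03 (SE; SDs over n = 3).

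Imbalance was called more often, and at smaller ratios, in deeply read regions. Regions with a mean of 20 to 50 assigned reads were called in 20.7% of cases, those with 50 to 100 in 26.4%, those with 100 to 1000 in 41.9% and those with 1000 or more in 66.4%. Calls of at least 2-fold ran the other way, at 16.0%, 10.8%, 6.75% and 6.63% of the regions in these classes. The median standard error of the log2 ratio was 0.36 in the lowest of these classes and 0.06 in the highest, and the lower quartile of the absolute log2 ratio of called regions was 1.02 and 0.22. Across the 33303 regions, the log2 ratios of 2 libraries correlated with Pearson's r of 0.825 to 0.842 and Spearman's rho of 0.584 to 0.596, and across the 2699 regions with 1000 or more reads with r of 0.985 to 0.990. Regions are not independent replicates. The spread between libraries was above binomial sampling, with a median chi-square of 1.40 times its expectation in the lowest class and 2.52 times in the highest.

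Imbalance was then compared between reads placed on one genome only and reads placed on both genomes but better on one. In 20143 regions tested with each kind, the kinds gave the same direction far more often than opposite ones. Of the 3822 regions called with both kinds, 3513 had the same direction, 2294 toward D. melanogaster and 1219 toward D. simulans, and 309 (8.08%) had opposite directions. Independent lists of these sizes would share 955 and 295 regions and oppose each other in 1082. The log2 ratios correlated across regions with r of 0.533 and rho of 0.552, and differed by 2-fold or more in 1720 regions (8.54%). The median ratio was 0.13 from reads placed on one genome and 0.05 from reads placed on both. Of the 8792 regions in this set that were called with all reads, 3513 were called in the same direction by each kind alone, 4537 by 1 kind, 120 in opposite directions and 622 by neither.

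**Figure D2:**
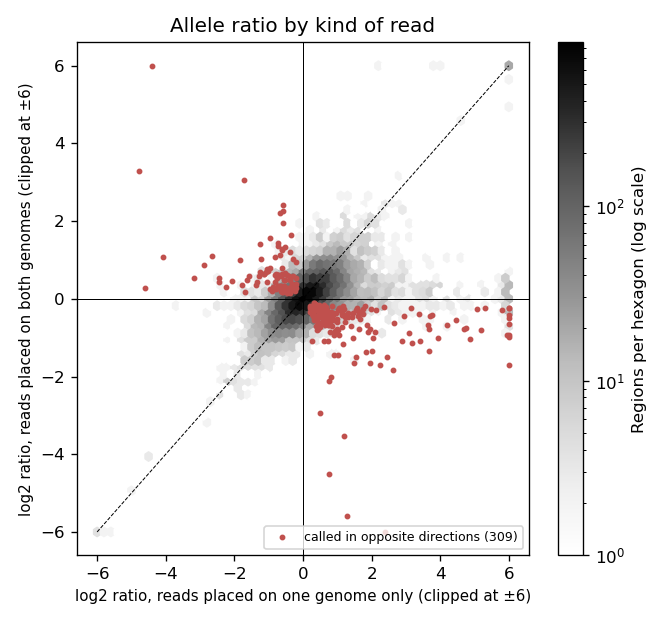
Log2 ratio of D. melanogaster over D. simulans reads from reads placed on one genome only (horizontal axis) and from reads placed on both genomes (vertical axis), clipped at 6 in each direction, for 20143 exonic regions shaded by their number per hexagon on a log scale. Red points are the 309 regions called in opposite directions, and the dashed line marks equal ratios.

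Imbalance was more frequent where the species' sequences differed more. Of the 1167 regions with over 99% identity, 20.6% were called, against 36.4% of the 8225 regions with 96% to 97% and 61.9% of the 328 regions with at most 90%. Calls toward D. melanogaster rose from 11.1% to 41.5% between the highest and the lowest class, and calls toward D. simulans from 9.51% to 20.4%. Across the tested regions, the absolute log2 ratio correlated with identity at a Spearman's rho of -0.180, and of -0.139, -0.134 and -0.147 in the single libraries. Read depth did not remove the relation, since among the 9852 regions with a mean of 100 to 300 assigned reads the called share was 61.3% in the lowest class and 27.5% in the highest. With reads placed on both genomes alone, the called share was 15.9% in the highest class and 43.1% in the lowest. With reads placed on one genome only, it was 63.4% in the lowest class and 30.3% at 97% to 98% identity, and 44.1% of the 222 regions over 99%.

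**Figure D3:**
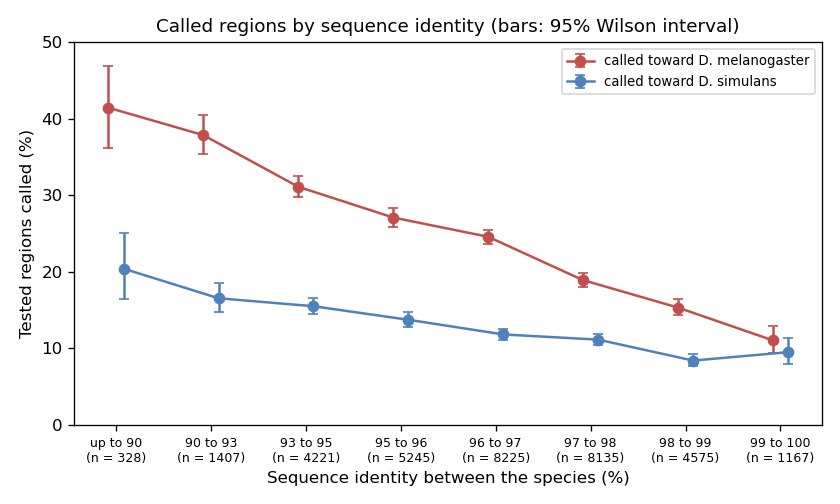
Percent of tested regions called toward D. melanogaster (red) or D. simulans (blue) by class of percent sequence identity between the species, with the number of regions in each class under the axis and bars for 95% Wilson intervals. Calls toward D. melanogaster fall from 41.5% to 11.1% and calls toward D. simulans from 20.4% to 9.51% between the lowest and the highest class.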

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

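The tests in this part were chosen after the data were seen, except for the share without the 100 regions with the most reads and the fit without the block. The first placement test of the regions at mitochondrial lengths was set before its own result, but those regions were picked after the data were seen. The unassigned reads, which entered no comparison of the alleles, held a signal of their own. In 1073 regions, the libraries had a mean of 20 or more unassigned reads but under 1 allele-assigned read, so that expression was seen and its allelic origin was not. These regions held 666276 reads, their median length was 123 bases, and 95.2% of them had 100% identity between the species.

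More reads came from D. melanogaster than from D. simulans. A few abundant regions were not the whole of it, since the median log2 ratio over tested regions was 0.0866 and was above 0 in each library. The D. melanogaster share was 53.9% with all regions, 51.9% without the 100 regions with the most reads, and 52.4% without the 19 abundant regions at mitochondrial lengths, whatever their ratio. The excess may also come from D. simulans reads lost where the species differ most, because the median ratio was 0.26 at up to 93% identity and 0.01 over 99%, a difference of 0.2516 (95% bootstrap interval 0.19 to 0.31). That interval takes regions as independent units and does not cover the spread between libraries. Regions with adjoining numbers leaned the same way, so it may be too narrow. A genuine excess of D. melanogaster or maternal transcripts stays open, as the genomic DNA control was not analysed here.

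Almost complete imbalance, with at least 98% of reads from 1 species, occurred in 334 regions, a threshold chosen after seeing the data. In 326 of them, 256 toward D. melanogaster and 70 toward D. simulans, a candidate explanation is that one reference cannot place reads of the region. Counting unassigned reads as placed on both genomes, a median of 1.7241% of their reads was placed there. The lower quartile was 57.0% in balanced regions matched on identity and length, and 241 of 293 matched regions lay below their own lower quartile. If lost placement left reads placed on both genomes balanced, such imbalance would need at most 4% of assigned reads there. This held in 250 of the regions and failed in 76. That balance was assumed and not tested. Reads of 1 species lost from both genomes would break it, so the 76 do not exclude lost placement. Complete silence of an allele, or its absence from a strain's genome, stays open in the 326 regions. For 1 of the 326, of 1788 bases and with 99.80% D. melanogaster reads, a mitochondrial origin also stays open. The number in its identifier lay among those of the almost complete regions at mitochondrial lengths, described next. Its log2 ratio was 9.26 with reads placed on both genomes.

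The other 8 regions, F8_SI among them, had at least 1000 mean reads and a D. melanogaster length exactly equal to a block of joined mitochondrial exons of at least 200 bases in the BDGP6 annotation, and D. simulans gave 0.0727% of their 1829777 assigned reads. They may be transcripts of the maternally inherited mitochondrial genome, with no D. simulans copy to be read: 8 of 24 abundant regions with almost only D. melanogaster reads matched such a length, against 11 of 2675 other abundant regions (Fisher's exact test, two-sided p = 7.6e-13). The depth limit and the way exons were joined were chosen after lengths had been seen to match, and the other 3 of the 4 ways tried gave 7 matches against 10 of 2675 (p = 3.1e-11 by the exact test) and, in 2 ways, 3 matches against 17 of 2675 (p = 0.000638 by the exact test). The placement test set before its own result also counted unassigned reads as placed on both genomes. It found a median of 55.6% of reads (55.598) there, under the matched lower quartile of 62.3%. Of the 8 regions, 5 lay under their own, as some loss of placement predicts. In a test chosen after the first, at least 34.7% (34.6723) of assigned reads were placed on both genomes in each of the 8, over the 4% limit. Both references could thus place reads of each region. Because the limit assumes balance among reads placed on both genomes, the test cannot exclude such loss as the whole cause. The numbers in the identifiers of these 8 regions lay close together, with that of the 1788-base region among them. This was seen after the data and was not tested.

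Other splits of the 6 allele columns were fitted for the count of called regions. Among the 4 splits that keep 1 column of each library in each group, 1, the real one, gave 11851 calls and the highest of the others gave 0. Among the 10 splits without the block, the real one gave 8024 and the highest of the others 0. These splits are too few for a share under 0.05. Each group of every other split also mixed columns of both alleles. Allele differences then widened the spread within groups, which by itself lowers the calls. The 0 calls thus do not show how many calls chance would give.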

How the results depend on the processing

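The alternatives by read kind, by reference change, by identity and without regions at mitochondrial lengths were chosen after the data were seen, as was leaving out replicates for the share of reads and the correlation with identity. Of the 11851 called regions, 10116 kept their call and direction with TMM scaling, 8024 without the replicate block and 5927 in the DESeq2 Wald test, with no region called in the opposite direction in these 3. Calls in the opposite direction numbered 74 with the strictest reads, 71 with reads placed on both genomes, 49 with reads placed on one genome and 28 with exactly matching reads.

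TMM scaling and DESeq2 size factors gave median log2 ratios of -0.005 and -0.0081, as centring does by construction, and D. melanogaster then made up 52.5% and 52.0% of calls. Fewer regions were called in total, toward D. melanogaster and toward D. simulans in the DESeq2 Wald test (5927, 4047 and 1880), in exact binomial tests (4855, 3313 and 1542), with the strictest reads (6124, 4297 and 1827), against a minimum log2 ratio of 0.5 (3719, 2628 and 1091) and in regions of equal length with no reference change (1082, 698 and 384). The last 2 settings and the strictest reads do so by construction, with a stricter hypothesis or with 3456 and 15707 regions tested. Without the replicate block 2553 regions were called toward D. simulans. Reads placed on both genomes gave 7468 calls, 4418 toward D. melanogaster, and reads placed on one genome gave 2646 toward D. simulans. The median ratio was 0.10 (0.0981) without a filter, 0.16 with the strictest reads, 0.10 (0.1011) with exactly matching reads, 0.0472 and 0.1417 with reads placed on both genomes or one, and 0.0735 in regions with no reference change. F19_SI reversed to -7.12 with the strictest reads and to -4.78 with reads placed on one genome.

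The D. melanogaster share of reads was 52.2% with the strictest reads, 51.9% without the 100 regions with the most reads, 55.1% and 51.9% with reads placed on both genomes or one, 55.5% with exactly matching reads, 52.4% (52.3986) without the 8 almost complete regions at mitochondrial lengths, which were picked by their ratio, and 52.4% (52.4080) without all 19 abundant regions at such lengths, and 53.8% to 54.2% when each replicate was left out. The rank correlation with identity was -0.136 and -0.138 with reads placed on both genomes or one, -0.192 at 100 to 300 reads and -0.172 to -0.161 when each replicate was left out. Leaving out each replicate gave 9150 to 9371 calls. Where no reason is given, the cause was not tested. Tests per gene, between exons, of gene lists and of chromosomes were not run, as regions could not be paired with genes. Depth limited precision, with a median standard error of 0.36 at 20 to 50 reads and 0.06 at 1000 or more.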

Other observations

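All comparisons in this part were chosen after the data were seen, and only the tests of the difference between read kinds were set before their own results. Regions with adjoining numbers in their identifiers tended to lean the same way. Among pairs of tested regions whose numbers differed by 1, the log2 ratios correlated with a Spearman's rho of 0.317, and the value was 0.224 at a step of 2, 0.0952 at 5, 0.0223 at 10 and 0.0103 at 50, against a maximum of 0.0239 in 1000 shuffles of the order. Where both regions of a pair with adjoining numbers were called, 3404 of 4174 pairs (81.6%) had the same direction, against a mean of 55.0% in the shuffles, and 770 pairs had opposite directions. Whether adjoining numbers mean parts of the same gene is not given in the sources used here.

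F19_SI, the region with the most reads, measured 2248 bases in D. melanogaster and 2247 in D. simulans. The mitochondrial ribosomal RNA genes and their adjoining tRNA genes span 2247 bases of the mitochondrial genome in the BDGP6 annotation, from 12670 to 14916. Among tested regions, 1 other lay within 1 base of that length, so length alone left the identity of F19_SI open. The number in its identifier directly follows that of an almost complete region at a mitochondrial length, of 939 bases. D. melanogaster took 58.6% of the assigned reads of F19_SI, against a median of 99.96% in the 8 almost complete regions at mitochondrial lengths. Of reads placed on both genomes it took 90.6%, against 99.88% in those regions, and of reads placed on one genome only it took 3.53%. Since the 2 kinds of read disagree in F19_SI, its share does not settle its origin either. The deposited coverage signal of the 2 genotypes, whose origin is not stated, correlated across the 33303 tested regions with the log2 ratio of the alleles, with r of 0.375 and rho of 0.414 on the log2(value + 0.1) scale. The median log2 coverage ratio was -0.71, opposite in sign to the median allele ratio of 0.09.

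Reads placed on one genome and reads placed on both gave different ratios in some regions. Sampling noise does not account for it, because the difference recurred between libraries, with a lowest r of 0.8576 and a Spearman's rho of 0.554 to 0.590 over 7779 regions with at least 300 reads of each kind. It may depend on the sequence difference between the species, but only slightly, as its median was 0.23 in the lowest tertile of identity and 0.21 in the highest, a difference of 0.0251 (95% bootstrap interval 0.012 to 0.041). Here too the interval takes regions as independent units and does not cover the spread between libraries. Errors in a strain's reference and differences between isoforms were not tested.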
